A study of Arabidopsis thaliana with 30 samples.

How the data were processed

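Total RNA of Arabidopsis thaliana explants, wild type Columbia-0, was hybridised to 30 one-colour Affymetrix ATH1 arrays. Per the labels, root segments and aerial organs of 10-day-old seedlings, grown at 22 °C with 16 h of light and 8 h of dark, were kept on callus-inducing medium for 0, 12, 24, 48 or 96 h, and about 5 µg of RNA was used for each biotin-labelled target. Each organ and time has 3 arrays, which the labels call biological replicates. Each array's group, time and replicate number were read from its title. The composition of the medium, the time of day of each harvest and any processing batch are not given in the sources used here.

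The deposited values are MAS5 signal, the background-corrected intensity of each probe set on a linear scale, with 1 value per probe set and array. MAS5 is named per the submitters' processing notes, and its version is not given in the sources used here. The deposited intensity values ran from 0.1 to 57102, with 0 values at or below 0 or missing. The mean of each array after trimming 2% of probe sets at each end was 500, so the arrays had been scaled to a common target before deposit. Detection calls were not used here. No pair of arrays was identical (0 pairs).

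The table holds 22810 probe sets. The 64 control probe sets were left out of all tests. Gene names came from a table of the platform's annotation from 2016, which gave 1 gene for 13513 probe sets and several genes for 503. The other 8794 probe sets are unnamed here, not without a gene. Of the 1-gene probe sets, 13436 were matched to a locus code in the reference gene table. Genes are printed by the symbol of that annotation or, where it gives none, by their locus code.

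Signals were analysed as log2(signal + 22), where the pseudocount of 22 is the 20th percentile of all values. A fold change is therefore on this scale and understates the change of dim genes. Where a group lies near background, the size of a fold depends on the pseudocount. No further normalization between arrays was applied. A probe set was tested if at least 3 arrays lay above 87.4, the 40th percentile of all values, which kept 16765 probe sets. Of these, 9188 have one gene, and 7577 are unnamed or have several. The ID of 593 tested probe sets ends in _s_at or _x_at, and these can hybridise with transcripts of related genes.

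Group means were fitted to all 30 arrays together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), so that the 10 groups shared one estimate of the spread. The tests were two-sided moderated tests with 28.6 degrees of freedom, adjusted by the Benjamini-Hochberg method over the 16765 probe sets within each comparison. A probe set was called at an adjusted p below 0.05, and calls of at least 2-fold were counted beside all calls. There were 17 comparisons of 2 groups or 2 changes: each later time against 0 h within each organ, root against aerial explants at each time, and the difference between the root and the aerial change at each later time. Moderated F tests asked, in 3 further tests, for any change over time in root explants, in aerial explants, and for any difference between the time courses.

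Gene lists, the genes to be named, the comparisons and the alternatives were fixed before the data were examined. Of 35 fixed lists, 8 had at least 5 measured members and were tested with limma's camera, using 1 probe set per gene (the one with the highest mean) and a preset correlation of 0.01 between the genes of a list, over 9049 genes. Another 21 lists had fewer than 5 measured members, whose values are given gene by gene, and 6 had none: regulators of the start of the cell cycle, root nutrient uptake, xylem and secondary wall, the embryo and seed programme, chromatin regulators, and the morning genes of the circadian clock. Because so few members were measured, 25 lists were added from the probe annotation, after the annotation was seen and before any comparison of values, and were adjusted as a family of their own. Lists hold locus codes chosen from general knowledge. A gene counts as measured if a tested probe set names it alone, so a gene not measured may still lie on an unnamed probe set. Camera was also run with the correlation estimated for each list, and that p is given wherever it ends a call.

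The named genes follow a fixed rule. They are the 6 genes with the largest rise and the 6 with the largest fall at 12 h and at 96 h in each organ, the 6 each way between the organs at 0 h and at 96 h, and the 5 each way for the difference between the changes at 96 h. Each had to be called, to have a probe set of 1 gene with a symbol, and to have values of the 2 groups that do not overlap (for the difference between the changes, in at least 1 organ). Only 1249 of the 9049 genes have a symbol other than a locus code, so larger changes may lie among genes that could not be named. The rule adds 32 key genes, of which 6 were measured (LBD16, LBD29, PUCHI, GH3.3, ARR15 and RCA), and the members of each fixed list with the largest called changes. Genes named outside this rule, in the lists added from the annotation and in the weighing of explanations, were chosen from their group after their values were seen, except AT4G33980, which was chosen before.

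The similarity of the organs was measured as Pearson's r across the tested probe sets for the 9 pairs of a root and an aerial array of each time, and as the mean distance of each array to the arrays of the other organ, compared between 0 h and 96 h by an exact permutation test, two-sided.

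The steps were tested on simulated data with the 16765 probe sets, with 100 changed at each fold. Each probe set was drawn independently of the others, and far fewer were changed than the real comparisons called. The simulation therefore cannot judge the preset correlation, and the rates for the real data may differ. For root explants at 12 h against 0 h, 51% of 2-fold and 92% of 4-fold changes were recovered with 10 false calls. For root against aerial explants at 12 h the shares were 60% and 93% (7 false calls), and for the difference between the 12 h changes 19% and 76% (7 false calls). The F test over time in root explants recovered 51% and 94% (8 false calls), and that of the difference between time courses 18% and 78% (1 false call). With nothing changed in aerial explants at 12 h, 0 probe sets were called. For root explants at 12 h, camera gave p = 2.24e-20 for a simulated list of 10 raised genes with the preset correlation and 5.55e-09 with an estimated one, and 0.85 and 0.852 for an unchanged list.

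Alternatives tried 1 at a time were another pseudocount or none, a stricter filter (above 268.9, the 60th percentile) or none, quantile normalization, centring each array on its median, leaving out cross-hybridising probe sets, eBayes without the trend, fitting only the groups compared, a threshold of 0.01, replicate number as a block, and leaving out each array. Figures were drawn with matplotlib 3.10.9.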

Results

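The 30 arrays covered root explants and aerial organ explants of Arabidopsis seedlings during the first 96 h on callus-inducing medium, with 3 arrays for each organ at 0, 12, 24, 48 and 96 h. The series concerns the early stage of callus induction. Median signal per array lay between 139.1 and 182.7, and 57.8% to 62.5% of probe sets lay above the signal of 87.4 used as the filter. Replicate arrays correlated with r between 0.946 and 0.976 across tested probe sets, which are not independent of each other. The log2 ratio of the 3' to the 5' GAPDH control probe sets ran from -0.061 to 0.957. With 3 arrays in each group, the number of arrays limits the precision of every value.

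Changes are given as log2 values ± standard error with n = 3 arrays in each group, with the p from limma adjusted over all 16765 tested probe sets. The p-values measure only the spread between these arrays. Rankings of single genes are over the 1249 genes with a symbol, not over all tested probe sets. Genes ranked by the size of their change were named only if all 3 values of one group lay above all 3 of the other. For differences between the organs' changes, this had to hold in at least 1 organ. Chance separates 3 arrays from 3 in 10% of cases, and more often where either organ suffices. The separation was a condition of naming, so it is no separate support. List members and key genes were not put through it. Centring each array on its median lowered the median change of all probe sets in root explants by -0.132, -0.125, -0.184 and -0.267 at 12, 24, 48 and 96 h, and the difference between root and aerial changes by -0.211, -0.205, -0.13 and -0.231. It moved the difference between the organs by 0.115 at 0 h and -0.117 at 96 h, and quantile normalization moved the root change at 96 h by -0.111. Small root changes are to be read against these shifts. Counts of list members are over all probe sets, and those adjusted over the list alone are given where they differ.

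Among the 6 key genes that were measured, 4 rose in both organs. LBD16, a LOB-domain transcription factor needed for lateral root formation, rose in root explants from a mean signal of 271 ± 42.8 (SD, n = 3) to 1901 ± 741 at 12 h, a log2 change of 2.64 ± 0.31 (adjusted p = 1.25e-07), and in aerial explants from 86.2 ± 48.6 to 618 ± 325, a change of 2.49 ± 0.31 (adjusted p = 5.13e-07). At 96 h the changes of LBD16 were 2.91 and 3.26, and the difference between them was -0.35 ± 0.438 (adjusted p = 0.524). PUCHI, an AP2/ERF factor of lateral root primordia, rose more slowly, by 1.09 at 12 h and 4.12 at 48 h in root explants, and in aerial explants by 2.31 at 24 h and 3.46 at 48 h (0.54 at 12 h, adjusted p = 0.236). The root rise of PUCHI at 12 h lost its call without root 12 h replicate 1 (0.753, adjusted p = 0.0947). GH3.3, an auxin-induced enzyme that conjugates auxin to amino acids, rose by 3.91 to 4.80 in root and by 5.07 to 5.80 in aerial explants over the 4 times, and the differences between the organs' changes did not pass the test.

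LBD29, a close relative of LBD16 that also acts downstream of auxin, followed a different course in each organ. In root explants it peaked at 24 h, with a change of 5.82 ± 0.442 (adjusted p = 2.56e-11), and stood at 2.46 ± 0.442 at 96 h (adjusted p = 2.84e-05). In aerial explants its change was 2.90, 3.95, 5.29 and 6.23 at the 4 times, reaching a mean signal of 2017 ± 371 at 96 h against 249 ± 51.9 in root explants. The difference between the organs' changes was 1.87 ± 0.625 at 24 h (adjusted p = 0.0192) and -3.77 ± 0.625 at 96 h (adjusted p = 1.09e-05). The 24 h difference lost its call without a pseudocount, and without root 0 h replicate 1 it was 1.49 (adjusted p = 0.0708) and without root 24 h replicate 1 it was 1.69 (adjusted p = 0.0504). ARR15, a cytokinin-induced response regulator, had low signals and fell in aerial explants at all 4 times, by 1.82 to 2.48, and in root explants by 1.26, 1.32 and 0.99 at 12, 24 and 96 h. Without a pseudocount its calls in both organs at 24 h and in root explants at 96 h were lost, and quantile normalization also ended the last of these. Its root calls also depended on single arrays, and without root 0 h replicate 1 its root changes were -1.05, -1.11 and -0.783 (adjusted p = 0.0828, 0.057 and 0.159). RCA, the activase of Rubisco, fell in aerial explants from 31816 ± 5159 to 4125 ± 1017 at 96 h, and its changes in root explants (0.22, 0.04, 0.08 and 0.00) did not pass the test.

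**Figure D1:**
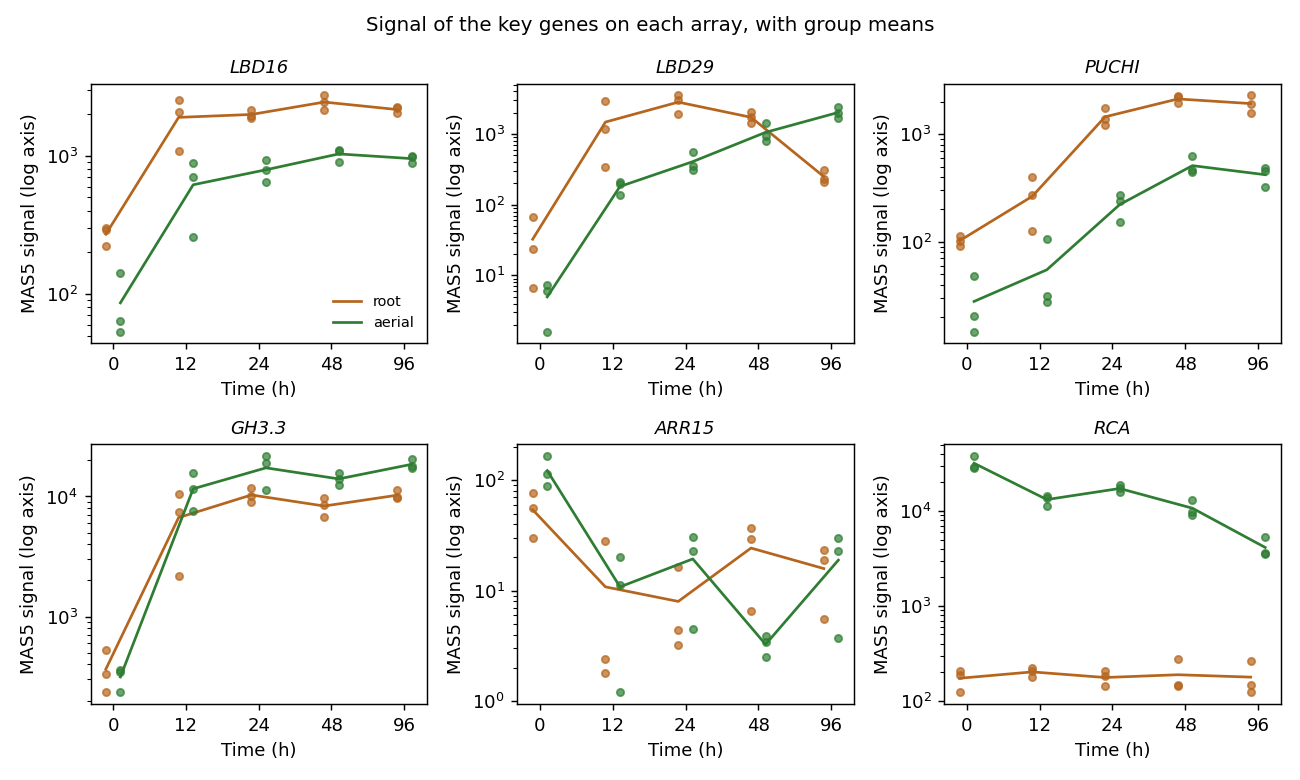
Signal of the 6 key genes on each array (points, log axis) against time on the medium, with lines through the group means of root (brown) and aerial (green) explants, n = 3. Mean LBD29 signal in root explants went from 32.5 at 0 h to 2820 at 24 h and 249 at 96 h, while in aerial explants it reached 2017 at 96 h.

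The root time course asked which genes change in root explants with time on the medium. No explants of either organ were kept off the medium. A change against 0 h therefore cannot be told apart from effects of cutting, age or time of day. At 12 h the largest rise among genes with a symbol was that of EXPA4, an expansin that loosens cell walls, from 599 ± 236 to 16991 ± 4734 (SD, n = 3), a 27.9-fold rise with a log2 change of 4.80 ± 0.229 (adjusted p = 3.76e-15). LBD29 rose by 4.47 ± 0.442, the subtilase SBT3.5 by 4.13 ± 0.498, the alkenal reductase AER by 4.12 ± 0.292, PPDK (pyruvate orthophosphate dikinase) by 4.05 ± 0.338 and GH3.3 by 3.91 ± 0.355. Without root 12 h replicate 2, whose LBD29 and GH3.3 signals were the lowest of the 3 arrays, LBD29 rose by 5.26 and GH3.3 by 4.58, without root 12 h replicate 1 LBD29 rose by 3.76, and without root 0 h replicate 1 SBT3.5 rose by 4.78. The largest falls among genes with a symbol were those of the AP2/ERF factor ORA47, which fell by 4.32 ± 0.581 (adjusted p = 1.05e-06), and of BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, which fell by 4.31 ± 0.594 (-3.31 without root 12 h replicate 1 and -5.14 without root 12 h replicate 2). GSTU20, a glutathione transferase, fell by 4.11 ± 0.348, XTH18, a xyloglucan-modifying enzyme, by 3.77 ± 0.284, and ATSBT5.2 and the glutaredoxin GRX480 followed at -3.76 ± 0.381 and -3.67 ± 0.455.

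By 96 h in root explants the largest rises among genes with a symbol were those of ARPN, a plantacyanin (41.1-fold, 5.36 ± 0.388, adjusted p = 3.04e-12), and of ICL, the glyoxylate-cycle enzyme isocitrate lyase (4.89 ± 0.795, adjusted p = 7.08e-06). GH3.3 rose by 4.80, the expansin EXPB2 by 4.70 ± 0.595, and the auxin-conjugating enzymes GH3.1 and WES1 by 4.55 ± 0.481 and 4.55 ± 0.336. BCAT4 went from 11113 ± 3061 to 28.3 ± 26.4, a fall of 236-fold (-7.88 ± 0.594, adjusted p = 6.78e-12). GAT1_2.1, a glutamine amidotransferase-like protein, fell by 6.68 ± 0.712 and GSTU20 by 6.61 ± 0.348. MSRB9, a methionine sulfoxide reductase (-5.93 ± 0.521), the dehydrin COR47 (-5.47 ± 0.322) and ZCF37 (-5.27 ± 0.481) also fell.

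Early auxin-response genes rose together in root explants. Of 7 measured members of this list, 6 rose at 12 h (7 adjusted over the list alone) and all 7 at 24, 48 and 96 h, with medians of 1.61, 2.82, 2.51 and 3.32. The list's adjusted p was 2.95e-04, 5.57e-05, 1.1e-04 and 1.73e-04, against 0.209, 0.127, 0.127 and 0.145 with an estimated correlation. GH3.3, GH3.1 and WES1 changed most, and IAA20, IAA29 and IAA30, which encode Aux/IAA proteins, rose by 3.04, 2.71 and 3.32 at 96 h. Genes of ribosome biogenesis also rose: 9, 10, 10 and 11 of 11 measured members at the 4 times, with medians of 1.304, 1.35, 1.28 and 1.35 (adjusted p = 1.58e-04, 5.57e-05, 5.02e-04 and 4.11e-04, and 0.313, 0.275, 0.234 and 0.231 with an estimated correlation). Among them RBL rose by 1.51 at 12 h, and NRPA1 and NRPA2, subunits of RNA polymerase I, rose by 1.38 and 1.304.

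Mitosis and cytokinesis genes moved later in root explants. At 12 h 1 of 5 measured members was down (AUR2, -0.99) and the list had a median of -0.54 (adjusted p = 0.161), and at 24 h 3 were up with a median of 0.83 (adjusted p = 0.122). All 5 rose at 48 and 96 h, with medians of 1.37 and 2.15 (adjusted p = 0.0269 and 0.0117, and 0.234 and 0.221 with an estimated correlation). The Aurora kinases AUR1, AUR2 and AUR3 rose by 2.15, 2.15 and 1.56 at 96 h, AT1G63100 by 2.19 and the spindle checkpoint gene BUBR1 by 1.01. Both measured members of the fixed DNA replication list, PRL, a helicase subunit of the MCM complex, and ICU2, the catalytic subunit of DNA polymerase alpha, rose from 24 h on and reached 1.84 and 2.16 at 96 h. SIM, an inhibitor of cyclin-dependent kinases, fell by 1.70 at 96 h.

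The heat shock list went the other way. All 6 measured members fell at 48 and 96 h, with medians of -2.36 and -3.46 (adjusted p = 5.02e-04 and 1.79e-04, and 0.22 and 0.15 with an estimated correlation). At 24 h 4 fell (median -1.48, adjusted p = 0.0285, and 0.478 with an estimated correlation), and at 12 h 3 were up and 0 down (median 0.52, adjusted p = 0.719). The small heat shock protein genes ATHSP22.0 (-4.08), AT1G53540 (-4.02) and AT2G29500 (-3.84) fell most at 96 h, with AT1G53540 at -4.61 without root 0 h replicate 3. Cell wall loosening genes split, with 4 up, 3 down and 1 not called at 96 h: EXPA4 (4.39), EXPA8 (2.75), EXPA15 (2.74) and EXPB3 (1.45) rose, and XTH18 (-4.40), EXPB1 (-1.41) and XTH19 (-1.23) fell. That list was not called at any time in root explants (adjusted p between 0.466 and 0.905), and at 12 h its median was -0.06 and its mean 0.32. The Calvin cycle and photosystem lists were not called in root explants either. The Calvin cycle and photorespiration median was 0.08 at 48 h with a mean of -0.23, and its sign turned under both other scalings.

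Smaller lists showed further changes in root explants. CR4, a receptor kinase of formative divisions, rose from 24 h on and by 3.66 at 96 h, where BBM, an AP2 factor of the root stem cell niche, rose by 3.26. The root hair expansins EXPA7 and EXPA18 rose by 3.17 and 2.96 at 12 h and by 2.18 and 2.095 at 24 h (EXPA7 by 2.78 without root 24 h replicate 1, and the EXPA18 call lost without root 0 h replicate 2, 1.53, adjusted p = 0.0587), and at 96 h their changes were -0.26 and -0.04, not called. All 3 measured hypoxia genes fell at every time, with AT3G10040 at -3.08, AT4G17260 at -2.14 and PDC2 at -1.23 at 12 h, the last call lost without root 12 h replicate 1 (-0.765, adjusted p = 0.0916). OPCL1, an enzyme of jasmonate synthesis, fell by 1.68 at 12 h and 2.00 at 96 h, while PDF1.2 was not called. In the phloem list OPS rose by 1.34 and the sucrose transporter SWEET11 fell by 3.07 at 12 h. The wound-related AP2/ERF gene AT5G61890 rose by 3.07 at 12 h (0.32 at 96 h, not called), and AT1G36060 rose by 1.88 at 96 h, or by 2.62 without root 96 h replicate 2 (-0.11 at 12 h, not called). The circadian clock gene GI fell by 2.42 at 12 h. The endodermal receptor kinase GSO1 fell by 1.45 at 96 h, the glycosyltransferase UGT73B5 by 2.08, GSTU25 by 1.35, ATG8E by 2.00 and AKINBETA1 by 1.11.

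Over the root time course, 6250, 7524, 8604 and 9581 of 16765 probe sets were called at 12, 24, 48 and 96 h, and 3477, 4405, 5209 and 6069 of these changed at least 2-fold. The calls were 3645 up and 2605 down at 12 h, 4540 and 2984 at 24 h, 5294 and 3310 at 48 h, and 6066 and 3515 at 96 h. With each array centred on its median the split was 2761 up and 3205 down at 12 h, 4077 and 4019 at 48 h, and 4312 and 4547 at 96 h. The F test called 10972 probe sets over the whole course.

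**Figure D2:**
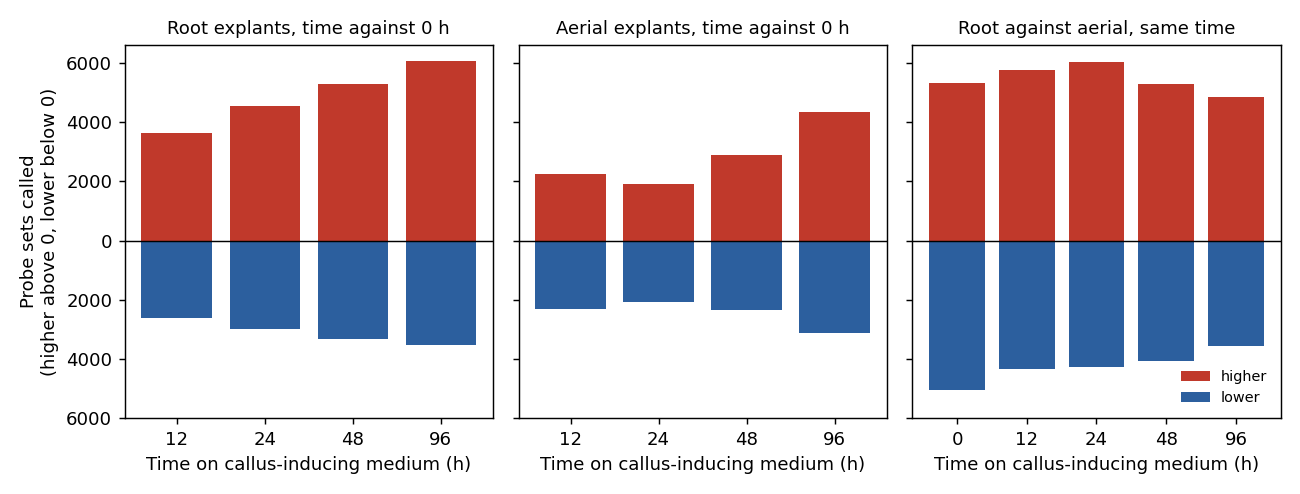
Number of probe sets called higher (red, above 0) and lower (blue, below 0) for each time against 0 h in root and aerial explants, and for root against aerial explants at each time. Root explants had 3645 up and 2605 down at 12 h and 6066 and 3515 at 96 h, splits that became 2761 and 3205, and 4312 and 4547, when each array was centred on its median; centring also turned the majority in aerial explants at 12 h (2262 up and 2315 down, then 2689 and 1997) and 24 h (1913 and 2077, then 2301 and 1709), and between the organs at 96 h (4847 higher and 3548 lower in root explants, then 3928 and 3967).

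The aerial time course asked the same of leaf and shoot tissue. At 12 h GH3.3 rose 33.6-fold (5.07 ± 0.355, adjusted p = 3.29e-11), from 315 ± 70.3 to 11588 ± 4003 (SD, n = 3). COR15A, a cold-regulated chloroplast protein, rose by 3.64 ± 0.602, CCL by 3.31 ± 0.397, the circadian clock gene GI by 3.25 ± 0.461 (adjusted p = 4.17e-06), XTH18 by 3.15 ± 0.284 and MGL, a methionine gamma-lyase, by 3.01 ± 0.393. CCL rose by 2.65 without aerial 0 h replicate 1 and GI by 2.64 without aerial 0 h replicate 2. HYH, a bZIP factor of light signalling, fell by 3.46 ± 0.49 (adjusted p = 4.15e-06). GSTU18 (-3.398 ± 0.35), the sugar transporter SWEET2 (-3.196 ± 0.385), AFR (-3.14 ± 0.321), the plastid envelope protein LrgB (-3.09 ± 0.324) and the thylakoid protein CaS (-2.99 ± 0.36) fell as well.

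At 96 h in aerial explants PR-1-LIKE went from 78.9 ± 53.1 to 18460 ± 2584, a 208-fold rise (7.70 ± 0.545, adjusted p = 2.83e-12). LBD29 rose by 6.23 ± 0.442, ALPHA-VPE, a vacuolar processing enzyme, by 6.19 ± 0.348, SAG29, a sugar transporter linked to senescence, by 5.92 ± 0.513, GH3.3 by 5.80 ± 0.355 and OSM34, an osmotin, by 5.20 ± 0.419. The largest falls among genes with a symbol were those of ECS1 (-5.26 ± 0.326, adjusted p = 1.99e-13), CaS (-5.12 ± 0.36), and the enzymes of photorespiration and the Calvin cycle HPR (-4.85 ± 0.374), SBPASE (-4.58 ± 0.396) and PRK (-4.36 ± 0.41). LrgB fell by 4.26 ± 0.324.

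Photosynthesis genes fell in aerial explants. All 5 measured genes of the Calvin cycle and photorespiration fell at every time, with medians of -1.98, -1.49, -2.50 and -4.36 (adjusted p = 2.69e-05, 3.7e-04, 3e-06 and 1.56e-07). Of 8 photosystem and antenna genes, 4 fell at 12 h and 4 at 24 h (5 and 6 adjusted over the list alone), and all 8 at 48 and 96 h. The medians of this list were -0.87, -0.74, -1.56 and -2.90 (adjusted p = 2.26e-03, 5.15e-03, 6.08e-06 and 4.86e-08, of which the first 2 became 0.15 and 0.183 with an estimated correlation). PSAN fell by 3.98, PSBY by 2.96 and LHCB4.2 by 2.90 at 96 h. All 4 measured chlorophyll synthesis genes fell at 96 h, CHLM by 3.05, PORB by 2.47, AT1G74470 by 2.37 and GSA1 by 1.56. The leaf polarity genes YAB3 and YAB5 fell by 1.97 and 1.13 at 96 h, the latter call lost without a pseudocount. SPCH, which starts the stomatal lineage, changed by -2.299 at 96 h and the trichome regulator TRY by -2.33, both called, while FMA was not called.

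Auxin-response genes rose in aerial explants, 5, 4, 6 and 6 of 7 at the 4 times, with medians of 2.01, 2.25, 2.81 and 3.02. The adjusted p was 2.69e-05, 4.08e-06, 1.31e-05 and 2.22e-04, and the calls at 12 and 96 h were lost with an estimated correlation (adjusted p = 0.0516 and 0.0721). Ribosome biogenesis genes rose at 12, 48 and 96 h, with 5, 5 and 8 of 11 called (7, 8 and 10 adjusted over the list alone) and medians of 0.57, 0.61 and 0.85 (adjusted p = 2.24e-03, 0.0103 and 1.46e-03, and 0.275, 0.476 and 0.315 with an estimated correlation). At 24 h 1 was called (0 adjusted over the list alone), and the median was 0.23 (adjusted p = 0.142). Mitosis and cytokinesis genes fell first: 4 of 5 at 12 h and 4 of 5 at 24 h, with medians of -1.39 and -1.17 (adjusted p = 1.19e-03 and 2.09e-03, and 0.0816 and 0.101 with an estimated correlation). BUBR1 fell by 1.57, AUR2 by 1.52, AUR3 by 1.39 and AUR1 by 1.17 at 12 h. At 48 and 96 h this list was not called (medians -0.35 and 0.51), and at 96 h AUR1 was up by 0.97 while BUBR1 was down (-0.9964), the latter call lost without a pseudocount, without the filter and without some single arrays. In the DNA replication list, ICU2 was not called, and the calls of PRL at 24 and 48 h (-0.64 at each) were lost without any of several single arrays.

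Stress and secondary metabolism genes also moved in aerial explants. The detoxification genes GSTU25, UGT73B4 and UGT73B5 rose at every time, by 2.89, 2.50 and 1.69 at 12 h, though the 24 and 96 h calls of UGT73B5 were lost without some single arrays (at both times without aerial 0 h replicate 2). All 3 flavonoid genes fell at every time, with UGT78D2, DFR and UGT78D1 at -2.52, -2.48 and -2.14 at 12 h, and DFR at -3.09 without aerial 0 h replicate 3. The leucine catabolism genes IVD and MCCA, held in the sugar starvation list, rose by 2.08 and 1.84 at 12 h, and IVD by 2.29 at 48 h. AT1G36060 rose by 2.90 and AT5G61890 by 1.62 at 96 h, SIM by 1.24 and OPCL1 by 1.21. The cytokinin-response gene RR16 fell by 1.21 to 1.56, calls that were lost without a pseudocount. BBM rose by 2.92 at 96 h (3.51 without aerial 0 h replicate 1), whereas CR4 and JKD were not called. SWEET11 fell by 1.37 at 96 h, and YUC2, a gene of auxin synthesis, by 1.15, a call lost without aerial 0 h replicate 1 (adjusted p = 0.0591). Of the hypoxia genes, AT4G17260 rose by 1.23 at 96 h, and PDC2 by 1.31 at 12 h, a call lost without aerial 0 h replicate 1 (0.896, adjusted p = 0.0731). EXPA7, EXPA18 and GSO1 were not called, and the calls of BCAT4 at 12 and 24 h were lost without some single arrays.

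Cell wall loosening genes again split in aerial explants, with 4 up and 3 down of 8 at 96 h: XTH18 (4.78), XTH20 (4.62), XTH19 (2.88) and EXPA4 (1.91) rose, and EXPB1 (-2.93), EXPA8 (-2.61) and EXPB3 (-1.69) fell. The list was not called (adjusted p between 0.0958 and 0.517), and its median was below 0 and its mean above 0 at 12, 24 and 48 h (-0.06 and 0.44, -0.19 and 0.83, -0.01 and 0.60). Heat shock genes had 0 calls of 6 at every time, with list adjusted p between 0.73 and 0.984. Their median, mean and test differed in sign at 12, 24 and 96 h. Of 6 cytosolic ribosome genes 4 were up at 96 h in aerial explants (6 adjusted over the list alone) and 4 at 24, 48 and 96 h in root explants (5 adjusted over the list alone at 96 h). That list was not called in either organ, but after quantile normalization it was called at 48 and 96 h in root explants (adjusted p = 0.024 and 0.0404) and at all 4 times in aerial explants (adjusted p = 0.0193, 0.0187 and 0.0238 at 12, 24 and 48 h, and lower at 96 h).

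In aerial explants 4577, 3990, 5251 and 7467 probe sets were called at 12, 24, 48 and 96 h, and 2500, 2125, 3108 and 4581 of these changed at least 2-fold. The calls were 2262 up and 2315 down at 12 h, 1913 and 2077 at 24 h, 2909 and 2342 at 48 h, and 4354 and 3113 at 96 h, and the F test called 7993 probe sets. The excess of falls at 12 and 24 h turned under both other scalings, to 2689 up and 1997 down at 12 h and 2301 and 1709 at 24 h with arrays centred on their medians, and to 2445 and 2143, and 2033 and 1881, after quantile normalization. Without aerial 0 h replicate 1 the 24 h count was 2589. Fitting only the groups compared gave 3009 calls at 12 h and 2549 at 24 h.

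**Figure D3:**
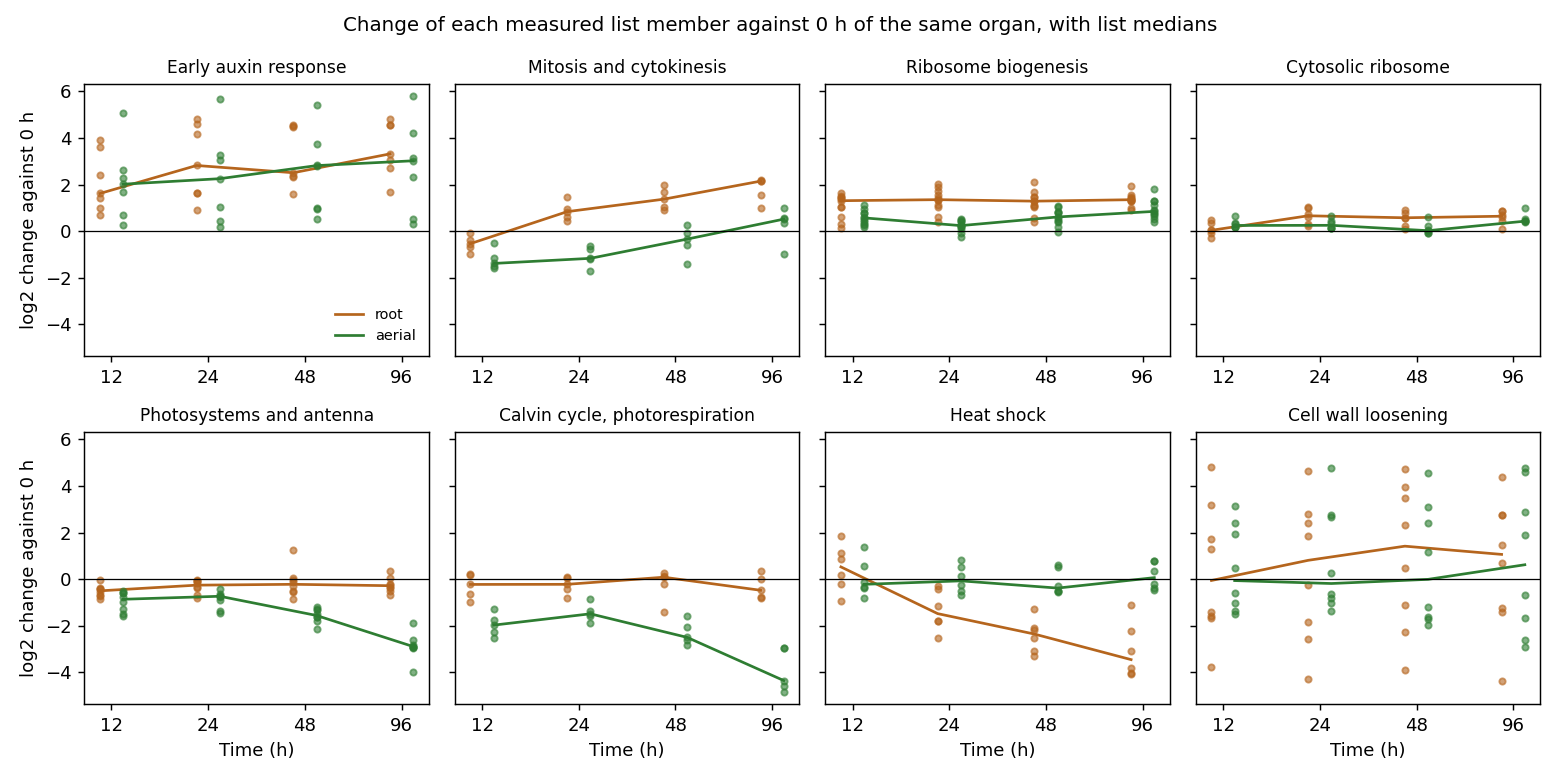
Log2 change against 0 h of each measured member (points) of the 8 tested lists, with lines through the list medians, in root (brown) and aerial (green) explants. At 96 h the Calvin cycle and photorespiration median was -4.36 in aerial explants, and the heat shock median was -3.46 in root explants; the near-zero medians of the heat shock list in aerial explants at 24 and 96 h, of the cell wall list in aerial explants at 12 h, of the cytosolic ribosome list in root explants at 12 h and aerial explants at 48 h, and of the Calvin cycle list in root explants at 48 h turned sign under another scaling.

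Root and aerial explants were compared with each other at each time, which asks how far the organs stay apart. At 0 h LTI30, a dehydrin, was 211-fold higher in root explants (29481 ± 6043 against 130 ± 72.9, SD, n = 3), a difference of 7.72 ± 0.365 (adjusted p = 5.1e-17). OSM34 was higher by 7.17 ± 0.419, the calmodulin-like gene CML38 by 7.06 ± 0.544, GRX480 by 6.83 ± 0.455, CCR2 (AT1G80820, a cinnamoyl-CoA reductase) by 6.51 ± 0.388 and GSTU25 by 6.18 ± 0.389. ECS1 was 428-fold higher in aerial explants (root minus aerial -8.74 ± 0.326, adjusted p = 3.19e-19), and the photosynthesis genes LHCB4.2, PSAN, HPR, PRK and SBPASE followed at -8.15, -8.12, -8.00, -7.96 and -7.94. RCA stood at -7.37 ± 0.238, at 173 ± 42.6 in root against 31816 ± 5159 in aerial explants. Without root 0 h replicate 1 PSAN stood at -8.75.

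At 96 h the genes higher in root explants were led by EXPB2 (4.14 ± 0.595, adjusted p = 1.78e-06), LTI30 (4.11 ± 0.365) and AGL42 (3.88 ± 0.292), followed by ICL (3.71 ± 0.795), PDF2.1 (3.67 ± 0.418) and AGL21 (3.17 ± 0.267). AGL42 and AGL21 are MADS-box factors expressed in roots. Higher in aerial explants were CCL (-6.11 ± 0.397, adjusted p = 4.23e-13), BCAT4 (-5.66 ± 0.594), SWEET11 (-5.53 ± 0.281), the chloroplast ATP synthase and photosystem I genes ATPC1 (-5.52 ± 0.366) and PSAE-1 (-5.42 ± 0.319), and GSTU20 (-5.40 ± 0.348). LBD16 and PUCHI were higher in root explants at all 5 times, by 1.51 and 1.37 at 0 h and by 1.16 and 2.15 at 96 h. LBD29 was higher in root explants at 12 and 24 h (2.44 and 2.73) and lower at 96 h (-2.91 ± 0.442, adjusted p = 4.06e-06). The 12 h difference was 1.73 without root 12 h replicate 1 and 3.23 without root 12 h replicate 2, and that of ICL at 96 h was 4.42 without aerial 96 h replicate 3.

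All 8 photosystem genes were lower in root explants at 0, 12, 24 and 48 h and 7 of 8 at 96 h, with medians of -7.71, -7.02, -7.07, -5.87 and -4.87 (adjusted p = 1.89e-08, 4.94e-10, 3.97e-10, 1e-10 and 6.7e-11). The Calvin cycle and photorespiration list had all 5 members lower at the first 4 times and 4 at 96 h, with medians of -7.94, -5.88, -6.54, -5.59 and -4.14 (adjusted p = 5.08e-06, 3.62e-06, 1.2e-06, 2.53e-06 and 6.27e-05). Heat shock genes were higher in root explants at 0 h (5 of 6, median 3.58, adjusted p = 6.57e-03) and at 12 h (6 of 6, median 3.06, adjusted p = 1.19e-03), calls that became 0.305 and 0.191 with an estimated correlation. At 96 h the heat shock median was -0.01 with a mean of 0.14 and a sign that turned under another scaling. Over the same 0 h arrays the GAPDH 3' to 5' log2 ratio was 0.311 ± 0.104 in root and 0.636 ± 0.3 in aerial explants (SD, n = 3).

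Ribosome biogenesis genes were higher in root explants from 12 h on, with 10, 11, 11 and 10 of 11 called and medians of 1.28, 1.60, 1.26 and 1.16 (adjusted p = 1.19e-03, 2.32e-05, 9.21e-05 and 3.19e-04, and 0.302, 0.179, 0.231 and 0.293 with an estimated correlation). At 0 h 7 were higher and 1 lower (8 and 1 adjusted over the list alone; median 0.86, adjusted p = 0.069). Mitosis and cytokinesis genes were higher in root explants at 48 h, 5 of 5, with a median of 1.13 (adjusted p = 0.0445, and 0.291 with an estimated correlation). At 24 h all 5 were higher as well (median 1.61, adjusted p = 0.0531, and 0.0487 after quantile normalization), and 4 at 96 h (median 1.17, adjusted p = 0.0993). The auxin, cytosolic ribosome and cell wall lists were not called between the organs. Median, mean and test differed in sign for auxin response at 0 and 12 h (medians 0.20 and -0.04, the latter turning sign under another scaling), for the cytosolic ribosome at 12 h and for cell wall loosening at 48 h.

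Genes of other lists set the organs apart at 0 h. The leaf genes YAB3 and YAB5 were lower in root explants by -4.00 and -3.13, SPCH by -2.20, CR4 by -3.32, RR16 by -3.13 and UGT78D1 by -4.93. The hypoxia genes AT4G17260, AT3G10040 and PDC2 were higher by 3.62, 3.28 and 2.95, OPCL1 by 3.62, UGT73B4 by 5.53, GI by 5.07 (4.47 without aerial 0 h replicate 2) and GSO1 by 1.18. Of the reference genes, GAPC2 (0.35) and AT2G28390 (-0.01) did not pass the test at 0 h, the calls of AT4G34270 (0.47) and PEX4 (-0.47) were lost without some single arrays, and over time GAPC2 fell in root explants by 0.57 to 0.75. In aerial explants GAPC2 was called at 48 h (-0.44) and 96 h (-0.46), but after quantile normalization its 48 h change was 0.0169 (adjusted p = 0.931) and the 96 h call was lost. The medians of the reference list turned sign between scalings in root explants at all 4 times, in aerial explants at 24 and 96 h, between the organs at 12 h and for the difference between the changes at 12 and 96 h.

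Between the organs 10397, 10086, 10304, 9345 and 8395 probe sets were called at 0, 12, 24, 48 and 96 h, of which 7311, 6724, 6941, 5864 and 4806 differed at least 2-fold. At 0 h 5341 were higher and 5056 lower in root explants, and at 96 h 4847 and 3548, where the split became 3928 and 3967 with arrays centred on their medians. The whole profiles moved closer. The mean r of the 9 pairs of a root and an aerial array was 0.477 (0.449 to 0.496) at 0 h, 0.624 at 12 h, 0.636 at 24 h, 0.703 at 48 h and 0.777 (0.761 to 0.8) at 96 h, while arrays within an organ and time had a mean r between 0.949 and 0.972. The mean distance of a root array to the aerial arrays was 1.99 ± 3.79e-03 at 0 h and 1.26 ± 0.0156 at 96 h (SD, n = 3), and that of an aerial array to the root arrays 1.99 ± 0.0506 and 1.26 ± 0.0407. The exact permutation test, two-sided, gave p = 0.1 for each, the smallest value that 3 arrays against 3 allow. Both organs' distances average the same 9 pairs at each time, so these tests are not separate. The 3 distances of an organ share the same opposite arrays and are not independent, so their SD is no spread between replicates. Without the filter on dim probe sets r was higher, 0.675 at 0 h and 0.864 at 96 h.

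The difference between the root and the aerial change asked which responses depend on the organ. Where a gene lay near background at 0 h in 1 organ it could not be seen to fall there, and unless it rose the difference restates the change in the other organ. At 96 h XTH18 had the largest difference among genes with a symbol (-9.18 ± 0.402, adjusted p = 2.29e-16), with a change of -4.40 in root and 4.78 in aerial explants. BCAT4 (-7.84 ± 0.84) fell by 7.88 in root explants and was at -0.04 in aerial explants, MSRB9 (-7.54 ± 0.737) went -5.93 and 1.61, GAT1_2.1 (-7.16 ± 1.01) went -6.68 and 0.49, and COR47 (-6.27 ± 0.455) went -5.47 and 0.80. In the other direction stood CCS, the copper chaperone of superoxide dismutase (5.54 ± 0.526, 3.94 in root and -1.60 in aerial explants), EXPA8 (5.36 ± 0.478, 2.75 and -2.61), UGT88A1 (5.20 ± 0.325, 3.29 and -1.91), LrgB (5.05 ± 0.458, 0.80 and -4.26) and TAPX, a thylakoid ascorbate peroxidase (5.02 ± 0.44, 0.77 and -4.25). All 5 had a mean root signal below 87.4 at 0 h (53.8, 6.13, 81, 8.3 and 17.1). GAT1_2.1 in turn stood at 25.4 in aerial explants at 0 h. RCA differed by 2.95 ± 0.337 (adjusted p = 2.95e-08), and CR4 by 4.13. Leaving out 1 array moved CCS to 6.19 (root 0 h replicate 1), MSRB9 to -6.83 (aerial 0 h replicate 1) and GAT1_2.1 to -7.76 (aerial 96 h replicate 3).

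At 96 h the changes differed for all 8 photosystem genes (median 2.47, adjusted p = 9.31e-04, and 0.171 with an estimated correlation), all 5 genes of the Calvin cycle and photorespiration (median 3.57, adjusted p = 9.31e-04, and 0.0584) and 5 of 6 heat shock genes (median -3.34, adjusted p = 2.78e-03, and 0.237). At 0 h 6 of the 8 photosystem genes and 3 of the 5 of the Calvin cycle and photorespiration (PRK, SBPASE and HPR at 47, 40.2 and 51.7) had a mean signal below 87.4 in root explants. In aerial explants 3 of the 6 heat shock genes did. For these genes the difference mostly restates the fall in the other organ. AT1G11860 (the glycine decarboxylase subunit GLDT) stood at 1118 in root explants at 0 h and was singled out for this after its values were seen. It changed by 0.34 there and by -2.98 in aerial explants. Mitosis and cytokinesis genes differed at 24 h, 4 of 5 (5 adjusted over the list alone), with a median of 2.12 (adjusted p = 5.99e-03, and 0.386 with an estimated correlation), and at 48 h, 5 of 5, with 1.68 (adjusted p = 0.0136, and 0.314). At 96 h 4 of 5 members differed (5 adjusted over the list alone), and the list had a median of 1.67 (adjusted p = 0.0675). Ribosome biogenesis differed at 24 h, 8 of 11 (9 adjusted over the list alone), with a median of 1.17 (adjusted p = 5.99e-03, and 0.464). Other calls were the Calvin cycle list at 12 and 48 h (medians 1.52 and 2.32, adjusted p = 0.0288 and 0.0136, and 0.259 and 0.27), heat shock at 48 h (-2.32, adjusted p = 0.0136, and 0.322) and photosystems at 48 h (1.17, adjusted p = 0.0267, and 0.322), the last of which was lost after quantile normalization (adjusted p = 0.0757).

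The auxin, cytosolic ribosome and cell wall lists were not called for the difference between the changes. Among cell wall genes EXPA8, EXPA15 and EXPB3 differed one way at 96 h (5.36, 3.41 and 3.13) and XTH18, XTH19 and XTH20 the other (-9.18, -4.12 and -3.94), and this list had a positive median and a negative mean at 12, 24 and 96 h. The auxin list at 12 h and the cytosolic ribosome list at 96 h had medians near 0 (0.02 and 0.05) that turned sign under another scaling. SIM differed by -2.94 at 96 h, OPCL1 by -3.21, GSTU25 by -5.47 and UGT73B4 by -3.82. The hypoxia genes AT4G17260, AT3G10040 and PDC2 differed by -2.60, -2.38 and -2.06, IVD by -2.51, SPCH by 2.12 and CHLM by 3.17.

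Changes differed between the organs for 5193, 6486, 7495 and 8716 probe sets at 12, 24, 48 and 96 h, 4196, 5188, 6222 and 7367 of them by at least 2-fold, and the F test called 10005. The calls were 2930 positive and 2263 negative at 12 h, 3818 and 2668 at 24 h, 4122 and 3373 at 48 h, and 4863 and 3853 at 96 h. With arrays centred on their medians the split was 1988 and 2957 at 12 h, 2664 and 3305 at 24 h, 3432 and 3737 at 48 h, and 3861 and 4577 at 96 h, and after quantile normalization it was 2428 and 2463 at 12 h.

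The overlap of the responses was counted from the calls of each organ, which share no control arrays. At 12, 24, 48 and 96 h 813, 692, 1092 and 1903 probe sets rose in both organs, where independent lists would give 492, 518, 919 and 1575. Those that fell in both numbered 424, 381, 406 and 615, where independent lists would give 360, 370, 462 and 653. Opposite calls numbered 682, 814, 1302 and 1885. Those up in root and down in aerial explants were 317, 433, 630 and 927, where independent lists would give 503.3, 562.5, 739.5 and 1126. Those down in root and up in aerial explants were 365, 381, 672 and 958, where independent lists would give 351.5, 340.5, 574.3 and 912.9. Each of the opposite probe sets was also called for the difference between the changes. Called changes of opposite sign in one fit all but fix that outcome, so it is no separate support. GH3.3, LBD16 and WES1 rose in both organs at every time, and XTH18 rose in aerial and fell in root explants at every time. Across genes, which are not independent replicates, Pearson's r between the root and aerial changes was 0.139, 0.109, 0.0873 and 0.0703 at the 4 times, and Spearman's rho was 0.133, 0.0664, 0.0434 and 0.0707.

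With an estimated correlation 18 of the 57 calls of the fixed lists held: auxin response in aerial explants at 24 and 48 h, the photosystem list in aerial explants at 48 and 96 h and between the organs at all 5 times, and the Calvin cycle and photorespiration list in aerial explants at all 4 times and between the organs at all 5.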

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

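The tests of regrouped arrays, of the return of clock genes at 24 h, of RNA degradation, of the scaling of the arrays and of the loss of dividing cells were chosen after the results were seen, and the others before. Each result in the next paragraph was set apart because the change over time differed between root and aerial explants in a test of the difference itself.

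The change differed for 5193, 6486, 7495 and 8716 probe sets at 12, 24, 48 and 96 h, and the whole time course for 10005. At 24 h the median differences of the changes (root minus aerial, log2) were 2.117 for mitosis and cytokinesis and 1.174 for ribosome biogenesis. At 96 h they were 2.473 for photosystems and antennae, 3.566 for the Calvin cycle and photorespiration, and -3.336 for heat shock. In the lists added from the annotation the 96 h values were 1.374 for plastid-encoded photosynthesis, 2.303 for plastid-encoded gene expression, 2.532 for nuclear genes of chloroplast function, 1.454 for organelle RNA editing and 1.217 for cell division. They were -3.073 for class III peroxidases, -1.536 for glutathione transferases, -0.8563 for autophagy (ATG8) and -1.745 for cold and dehydration genes. With an estimated correlation, the call of nuclear genes of chloroplast function held (adjusted p = 0.0142) and the calls of the other 13 of these lists were lost (adjusted p between 0.0584 and 0.516). Some of these genes were near background at 0 h in 1 organ, where a further fall cannot be seen: 6 of 8 photosystem and 3 of 5 Calvin cycle genes lay below a mean signal of 87.4 in root explants, as did 12 of 41 plastid-encoded photosynthesis, 1 of 18 plastid gene expression, 21 of 43 nuclear chloroplast and 9 of 11 RNA editing genes, and in aerial explants 3 of 6 heat shock, 12 of 25 peroxidase and 6 of 13 glutathione transferase genes did. For genes that start there, the difference can restate the fall in the other organ. Among single genes at 96 h the differences were 5.541 for CCS, 5.359 for EXPA8, 5.199 for UGT88A1, 5.052 for LrgB, 5.016 for TAPX, -9.181 for XTH18, -7.845 for BCAT4, -7.539 for MSRB9, -7.164 for GAT1_2.1, -6.269 for COR47, -3.774 for LBD29 and 2.953 for RCA.

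Other splits of the same arrays were tried for each count of probe sets. For the 13 comparisons of 3 arrays with 3, the 10 possible splits are too few for a share under 5%, and in each 1 of 10 splits, the real one, gave as many calls. The real and the highest other counts were 6250 and 36, 7524 and 3, 8604 and 0, and 9581 and 0 in root explants at 12, 24, 48 and 96 h. In aerial explants they were 4577 and 13, 3990 and 10, 5251 and 26, and 7467 and 17, and between the organs from 0 to 96 h they were 10397 and 0, 10086 and 1, 10304 and 1, 9345 and 0, and 8395 and 1. Among 100 splits of the time courses, 1 gave as many calls as the real one in root explants (10972, highest other 4214) and 1 in aerial explants (7993, highest other 4211), the real one in each case. Fewer than 5% of the splits drawn thus gave as many. Splits that mix arrays of different times widen the spread, and the smallest share possible is 1 of 100, so chance is not excluded.

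For the difference between the changes, 12 of 100 splits gave as many calls as the real one at 12 h (5193, highest other 8555), 12 at 24 h (6486, highest other 8302) and 6 at 48 h (7495, highest other 8553). At 96 h 1 of 100 did (8716, highest other 7808) and for the whole time course 2 (10005, highest other 10076). The splits with such counts point to a structure of the samples: all 11, 11 and 5 other splits as large at 12, 24 and 48 h, and the 1 for the time course, exchanged unequal numbers of arrays between the organs at the times compared and so carried the difference between the organs. The 42 other splits that exchange equal numbers at both times mix the organs within each group, which widens the spread, and gave at most 1 call. The difference between the organs fixes both outcomes, so these splits decide nothing about chance. The same splits were therefore counted again with the mean of each organ over the times compared removed for each probe set, which leaves the real counts as they were. Then 1 of 100 splits, the real one, gave as many calls in each case, with a highest other count of 2306, 2545, 3817 and 4927 at 12, 24, 48 and 96 h and of 3938 for the time course. Fewer than 5% of the splits drawn thus gave as many for these 5 counts. These splits still mix arrays whose changes differ, which widens the spread, and the smallest share possible is 1 of 100, so chance is not excluded.

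The pattern weighed here was an organ difference at 0 h in GI, a gene that cycles through the day. GI stood at a mean signal of 1994 in root and 47.3 in aerial explants at 0 h, and at 372 and 581 at 12 h. AT4G33980 stood at 856 and 84.2 at 0 h. COR27 showed no such difference, with 254 ± 112 in root and 216 ± 140 in aerial explants at 0 h (SD, n = 3). Its difference of 0.35 ± 0.507 did not pass the limma test (adjusted p = 0.563). A candidate explanation is that the 0 h arrays of the organs were taken at different times of day. A locus not looked at before, AT4G33980, had a difference of the 12 h changes of -2.93 (adjusted p = 2.43e-04), as that explanation predicted. Any gene higher in root explants only at 0 h, whatever the reason, would give such a value, so it does not single out time of day. The differences of AT4G33980 at 24, 48 and 96 h were -2.86, -3.22 and -2.50, with no return at whole days. In root explants AT4G33980 and COR27 fell further at 24 h (-2.65 and -1.59) than at 12 h (-1.75 and -1.27). GI fell less far there (-1.01 against -2.42). The return at 24 h left the explanation undecided. The mean absolute change of the 3 genes at 24 h minus that at 12 h was -0.0619 in root and -1.21 in aerial explants. The fixed test of time of day was void for root and for aerial explants at 12 h, with 0 morning clock genes named among the tested probe sets for each. The annotation used sets this limit, since unnamed probe sets may hold such genes. A response to cold or handling stays open and was not tested, because COR27 and AT4G33980 also respond to cold and cold and dehydration genes such as LTI30 and COR47 were high in root explants at 0 h.

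Another pattern was the high level of heat shock genes in root explants early in the course. Their mean log2 signal was 9.70 ± 0.942 in root and 6.36 ± 0.317 in aerial explants at 0 h and 10.18 ± 0.965 and 6.41 ± 0.121 at 12 h (SD, n = 3), and 6.64 ± 0.0447 and 6.50 ± 0.102 at 96 h. A single array was argued against as the source, because the lowest root 0 h array exceeded the highest aerial one by 2.12. RNA degradation was left undecided: the GAPDH 3' to 5' log2 ratio differed by -0.326 between the organs at 0 h, but the 0 h arrays lay between 0.198 and 0.957, so their difference could not have reached the bound of 1 set for it. Handling of the roots and a difference between the organs that the design names both stay open as hypotheses, and neither was tested.

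The last pattern was that mitosis and cytokinesis genes moved apart at 24 h, by a median of 2.12. With each array centred on its median, the median over the list was 1.91. Centring moves this difference by -0.205 for every probe set alike, so the value was fixed by that shift and is no separate test. It shows only that the pattern is large beside the shift from this scaling. Loss of dividing cells from the aerial explants cannot be told apart from a lower expression in the cells that remain. At 12 h in aerial explants the mitosis median was -1.39 while the replication genes PRL, POLA3, POLD3, PSF2 and ICU2 had a median of 0.0923, a gap of 1.48, but replication genes are also used by endoreduplicating cells, which keeps the explanation open. A biological difference between root and aerial explants may lie behind the pattern and was not tested.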

How the results depend on the processing

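The lists added from the annotation, and their recomputed tests, were not among the alternatives fixed in advance. The counts of probe sets called, and of those called the same way in both organs (1237, 1073, 1498 and 2518 at 12, 24, 48 and 96 h), were recomputed under each alternative and without each array in turn, while opposite calls were not. Outside the alternatives named in the next paragraph, each of these counts stayed within 1.5 times its value in the report, apart from 1 array named below. The test of the difference between time courses uses all arrays, so fitting only the groups compared gave no separate value for it, and a block within each organ was run only for changes over time.

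A threshold of 0.01 gave 2915 and 2258 probe sets in aerial explants at 12 and 24 h, and 3149 and 4157 for the difference between the changes at 12 and 24 h, because the threshold is stricter, and 640, 517, 858 and 1548 shared between the organs at the 4 times. Fitting only the groups compared gave 3009 and 2549 in aerial explants at 12 and 24 h, where fewer arrays estimate the spread, and 741 and 700 shared between the organs. Requiring at least 2-fold in both organs lowered the shared probe sets to 523, 467, 676 and 1082 by construction. Without the filter, the correlation of root and aerial profiles was 0.675, 0.768, 0.774, 0.824 and 0.864 from 0 to 96 h, with more genes in the comparison. With an estimated correlation 18 of 57 calls of the fixed lists and 16 of 143 of the added lists held. GAPC2 in aerial explants at 48 h changed direction under quantile normalization, to 0.0169 (adjusted p = 0.931), and the cause was not tested.

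Leaving out 1 array at a time gave 5114 to 6053, 6555 to 6981, 7639 to 8031 and 8563 to 9008 probe sets in root explants, and 3388 to 4279, 2589 to 3722, 4186 to 5014 and 6578 to 6967 in aerial explants, where 2589 came without aerial 0 h replicate 1. Between the organs the ranges were 9633 to 9905, 9248 to 9554, 9504 to 9763, 8250 to 8883 and 7191 to 7574, and for the difference between the changes 4385 to 5367, 5628 to 6206, 6797 to 7203 and 8042 to 8567. The time-course tests gave 10149 to 10877 in root explants, 7180 to 8087 in aerial explants and 9393 to 10118 for the difference. Probe sets shared between the organs numbered 995 to 1249, 780 to 1013, 1207 to 1459 and 2130 to 2392. Fewer arrays in the groups concerned lowered most of these counts.

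Under the other settings the ranges, lowest at a threshold of 0.01 in each case, were 4307 to 6753, 5625 to 7943, 6733 to 8992 and 7709 to 9987 in root explants and 2915 to 5094, 2258 to 4565, 3575 to 5761 and 5633 to 7898 in aerial explants. For single genes, 23658 of 25012 recomputed results were counted as unchanged, 1331 lost the call, 22 gained it and 1 called result reversed. Unchanged results kept direction and side of the threshold, or were not called at first and turned direction. Apart from left-out arrays, most losses came from fitting only the groups compared (107), no pseudocount (95), median centring (84), no filter (56) and quantile normalization (46). Of the root calls at 96 h, 8491 of 9581 were shared with quantile normalization and 7827 with median centring. Quantile normalization ended 1 of the 57 calls of the fixed lists and added 7, and it ended 13 of the 143 of the added lists and added 4, and the cause was not tested. The lists whose median changed sign under a scaling were not called in the main fit. After quantile normalization 1 of them, the cytosolic ribosome list in aerial explants at 48 h, was called.

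Replicate numbers were not taken to pair the arrays, because the labels give them no shared culture or day, but they were tried as a block. With replicate number as a block the counts were 6579, 7790, 8876 and 9843 in root explants, 4883, 4356, 5585 and 7752 in aerial explants and 5596, 6805, 7780 and 8967 for the difference between the changes, and with a block within each organ 9987 and 7898 at 96 h. Residuals of arrays of an organ with the same number correlated with a median r of 0.0921 (-0.117 to 0.389, 60 pairs) those of different organs with the same number with 0.0227 (-0.0906 to 0.19, 75 pairs), and those of other groups with another number with -0.0236 (-0.338 to 0.165, 270 pairs). Above 0.1 were 27, 6 and 11 of these pairs. Of 30 arrays, 24 were closest to arrays of their own number, where chance would give 10. Arrays of the same number thus share some variation, which the main fits do not model. Each count given here with a block is above that of the main fit.

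Arrays have no sequencing depth. Signal over background limits the dim genes, such as ARR15 and RR16, where leaving out the pseudocount ended calls.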

Other observations

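The lists in this part were added from the probe annotation, and none was chosen by its values, while the genes named from them as examples were chosen after their values were seen. Counts are over all probe sets, with those adjusted over the list alone where they differ at 96 h, and the list p-values form a family of their own.

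Chloroplast genes fell together in aerial explants. Of 43 nuclear genes of chloroplast function, 40 fell and 1 rose at 96 h (median -2.71, adjusted p = 8.72e-28), with NdhL (-4.22) and NdhN (-4.04), subunits of the plastid NADH dehydrogenase-like complex, and the thioredoxin TRXF2 (-3.67) among them. In root explants TRXF2 rose by 1.25, and the changes of this list differed between the organs by a median of 2.53 (adjusted p = 2.1e-13), though 21 of the 43 lay below a mean signal of 87.4 in root explants at 0 h and could not be seen to fall there. Genes encoded in the plastid genome fell too: 35 of 41 photosynthesis genes at 96 h (38 adjusted over the list alone; median -1.51, adjusted p = 1.12e-12, and 0.242 with an estimated correlation) and all 18 genes of plastid gene expression (median -2.01, adjusted p = 1.02e-09, and 0.242). The largest falls among them were those of rbcL (-3.24), psbN (-3.17) and rpoC2 (-2.62). Organelle RNA editing genes fell at 48 h (5 of 11 down and 1 up, median -0.64, adjusted p = 0.0458, and 0.384), and CRR21 stood at -2.30 at 96 h.

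Genes of growth rose in root explants. Of 31 cell division genes 28 rose and 1 fell at 96 h (median 1.77, adjusted p = 3.13e-06, and 0.271 with an estimated correlation), led by 3xHMG-box2 (2.74), TOPII (2.68) and Haspin (2.47), with ATMAP65-6 at -1.11. In aerial explants 12 fell and 1 rose at 12 h (median -0.61, adjusted p = 3.58e-04, and 0.319). All 32 ribosome biogenesis genes rose in root explants at 96 h (median 1.36, adjusted p = 7.65e-07, and 0.293) and 24 in aerial explants (26 adjusted over the list alone; median 0.91, adjusted p = 8.81e-06, and 0.351). Of 101 cytosolic ribosomal protein genes 78 rose in root explants at 96 h (82 adjusted over the list alone; median 0.65, adjusted p = 4.11e-06, and 0.641) and 73 in aerial explants (78 adjusted over the list alone; median 0.72, adjusted p = 3.9e-10, and 0.351). All 12 RNA polymerase subunits rose in root explants at 96 h (median 1.19, adjusted p = 4.5e-03, and 0.216), and 6 of 7 core histone genes rose in aerial explants (7 adjusted over the list alone; median 0.95, adjusted p = 0.0323, and 0.242).

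Several stress and redox lists were called. Glutathione transferases fell in root explants at all 4 times, 10 of 13 at 96 h with 0 up (1 up adjusted over the list alone; median -1.78, adjusted p = 7.44e-06), among them GSTU20 (-6.61), ATGSTF13 (-4.15) and GSTU26 (-3.71). In aerial explants the medians of this list were also below 0 (-0.489, -0.363, -0.144 and -0.623 at the 4 times) and it was not called. Class III peroxidases rose in aerial explants at 96 h, 14 of 25 up and 2 down (15 and 4 adjusted over the list alone; median 1.64, adjusted p = 6.1e-04, and 0.242 with an estimated correlation), with AT5G64100 at 6.71. In root explants 12 fell and 6 rose (median -1.19, adjusted p = 0.022, and 0.407, and 0.0686 after quantile normalization), with AT3G01190 at -6.46 and AT5G58390 at 5.09. Cold and dehydration genes fell in root explants at 24 h (6 of 10, 7 adjusted over the list alone; median -1.23, adjusted p = 6.73e-03, and 0.183) and rose in aerial explants at 12 h (5 of 10, median 1.00, adjusted p = 0.0271, and 0.319). The root calls of this list at 12, 48 and 96 h were lost after quantile normalization.

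Smaller groups were called at some times only. Tubulin genes fell in root explants at 12 h (4 of 7, median -0.66, adjusted p = 0.0191, and 0.272 with an estimated correlation), with TUB1 at -2.84, and rose in aerial explants (4 of 7, median 0.65, adjusted p = 0.041, and 0.325), a call lost after quantile normalization. Branched-chain amino acid catabolism rose in aerial explants at 12 h (6 of 8, median 1.02, adjusted p = 4.32e-03, and 0.319), and the ATG8 and autophagy list at 48 h (5 of 10, median 0.70, adjusted p = 0.0131, and 0.384). Cell wall enzymes rose in aerial explants at 24 h (9 up and 3 down of 28, median 0.38, adjusted p = 2.04e-03, and 0.36). SWEET transporters fell in both organs at 12 h, 4 of 9 in root (median -0.42, adjusted p = 0.042, and 0.272) and 3 of 9 in aerial explants (median -0.44, adjusted p = 0.0225, and 0.319). Iron homeostasis genes fell in root explants at 48 h (4 of 7, median -0.82, adjusted p = 0.0354, and 0.206), and ER body genes in aerial explants at 48 h (2 of 6, median -0.76, adjusted p = 0.0436, and 0.416), calls that quantile normalization ended (0.0535 and 0.159).

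In the remaining 6 added lists no comparison was called. Their lowest adjusted p was 0.082 for UDP-glycosyltransferases (36 measured), 0.111 for ER protein folding (13), 0.12 for central carbon metabolism (11), 0.0945 for lateral organ factors (11), 0.19 for reproductive cells (6) and 0.0995 for gibberellin signalling (7). With an estimated correlation 16 of the 143 calls of the added lists held: nuclear chloroplast genes in aerial explants at all 4 times, between the organs at all 5 and for the difference at 96 h, and glutathione transferases in root explants at all 4 times and for the difference at 24 and 48 h.

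The control probe sets for 25S ribosomal RNA ranged from a log2 signal of 10.86 (root 12 h replicate 2) to 14.07 over the 30 arrays. The same array had the highest heat shock mean of the root 12 h arrays, 10.99 against 9.11 and 10.44.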
